A study of Penicillium italicum with 6 samples.

How the data were processed

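Poly(A) RNA sequencing of Penicillium italicum spores was analysed in 6 libraries, 3 from control spores and 3 from spores incubated with exosome-like nanoparticles, named in the labels as biological replicates. Per the labels' protocols, messenger RNA was selected on oligo(dT) beads and fragmented, and the second cDNA strand was marked with dUTP, so the library keeps the strand. Adapters carried unique molecular identifiers, and read pairs were sequenced on a NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, without their role or order. The genome build, the strand setting in counting, the handling of reads that map to several places and the use of the molecular identifiers are not given in the sources used here. Values of paralogous genes and of the 11 tested genes that overlap another model are therefore uncertain.

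The deposited table holds, per the file headers, whole-number read counts per gene, and these were used for all main tests. It also holds, per the file headers, FPKM values that the authors computed, which were proportional to the counts within each gene once a factor per library was allowed for, and were used for the abundance filter and for part of the alternatives. Column names give the group by the abbreviations CK and Ex with a replicate number, and CK was read as control. Each of 9225 gene models has a GLEAN identifier and a position on a scaffold; 9184 have a description, 8305 a GO term and 3177 a KEGG pathway. Gene names are the file's own descriptions, which often name a protein domain, and 2881 tested genes are described only as hypothetical, uncharacterised or of unknown function. No reference genome was used here.

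Genes entered the tests with FPKM of at least 1 in at least 3 of the 6 libraries, which left 7907. The design fixed before the data were examined foresaw limma on log2 FPKM, or edgeR's quasi-likelihood test should the table hold counts, and since it holds counts the latter was used. Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), group was the sole term of the model, and Benjamini-Hochberg adjusted p under 0.05 over all tested genes was a call. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of the F statistic. Abundances are CPM, that is counts scaled to the library total with the TMM factors. The replicates of a group differed by more than sampling noise, with a chi-square per gene between 6.88 and 22.2 against 818 to 893 between groups, so none was treated as a repeat of another. Library totals ran from 51911076 to 58425767 counts, which at 10 CPM gives a counting error of 4.14 to 4.39%.

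Gene lists were fixed as search patterns over the descriptions before the data were examined. Of 28 lists, 25 had at least 5 tested members and were tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted over the lists, and again with an estimated correlation and with fry. Of the 4 lists called by camera, 0 were called with an estimated correlation, where 3 lists had an unadjusted p under 0.05. Fry called 17, but it asks whether the genes of a list move on balance in 1 direction and not whether they differ from other genes. GO and KEGG terms of 5 to 500 tested genes were tested for enrichment with Fisher's exact test, 1-sided, against all tested genes carrying any term of that source, adjusted over the terms of both sources and both directions. The same test on genes changed at least 2-fold was added after the data were seen.

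Genes were named by a rule fixed beforehand. It took, in each direction, the 8 called genes of largest log2 fold change with a functional description, no overlap between the groups and a mean FPKM of at least 10 in the higher group, and the 2 largest whatever their description. It also took up to 4 members of smallest p from each tested list, all members of smaller lists, and the 5 genes of highest mean FPKM. Of these, most are given in the text, and genes named outside the rule are marked as chosen after their values were seen.

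The procedure was tested on simulated counts for the 7907 genes, with 200 changed, 50 at each of 4 sizes. It recovered 50% of changes of 1.2-fold, 82% of 1.5-fold, 96% of 2-fold and 100% of 4-fold, with 13 false calls among 7707 unchanged genes. The data gave 5925 calls, far more than the 200 changed genes simulated. Recovery and false calls at such a share of changed genes were not tested. Alternatives covered the pseudocount, the abundance filter, the scaling, the replicate number as a block, the limma settings, DESeq2 1.42.0, leaving out each library in turn and leaving out replicate 3 of both groups. Pseudocount, quantile and limma alternatives were run on log2 FPKM, and upper quartile and median-of-ratios scaling as scalings of the counts in edgeR. Figures were drawn with matplotlib 3.10.9.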

Results

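Messenger RNA was sequenced from spores of Penicillium italicum, the fungus that causes blue mold of citrus fruit. The 6 libraries came from 3 biological replicates of control spores and 3 of spores incubated with exosome-like nanoparticles, which are vesicles, here isolated from orange juice. The series title concerns inhibition of the mold by microRNAs in these vesicles, and the comparison asked which transcripts of the spores differed after incubation. Total counts were 51911076, 53510959 and 53932388 in the control libraries and 58425767, 55950894 and 56000576 in the exosome libraries. Of the 9225 gene models, 7907 were abundant enough to be tested. Abundances are given in CPM, counts scaled to library size, as mean ± SD over n = 3 libraries per group, and log2 fold changes are exosome over control. At this depth, counting alone gives a coefficient of variation of 4.39% for a transcript at 10 CPM in the smallest library.

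Spores incubated with the nanoparticles had more transcripts of the ribosome, and fewer of the genes annotated to carbon utilization, than control spores. Of 79 cytosolic ribosomal protein genes, 69 rose, 2 fell and 8 were not called (camera adjusted p = 7.28e-17, but adjusted p = 0.281 with an estimated correlation). Ribosomal protein L1 (GL_Gan1_GLEAN_10001459; scaffold 301, 135280 to 136117) went from 294 ± 25.1 to 1089.6 ± 21.8 CPM. Of 20 genes annotated to carbon utilization, 16 fell (Fisher's exact test, adjusted p = 0.00411), and malate synthase A of the glyoxylate bypass (GL_Gan1_GLEAN_10003326; scaffold 144, 71658 to 73277) went from 4603 ± 99.4 to 1084 ± 34.7 CPM. The 2 groups of libraries separated along the first principal component, which held 89.1% of the variance of the log2 values. In all, 2999 genes were higher and 2926 lower with exosomes, and 1982 were not called. Changes of at least 2-fold were found in 611 of the higher and 576 of the lower genes, and of at least 4-fold in 63 and 85. The 2-fold counts depended on the scale, with 200 higher and 331 lower at a pseudocount of 5 on log2 FPKM. The median log2 fold change of the 7907 genes was 0.0040.

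**Figure D1:**
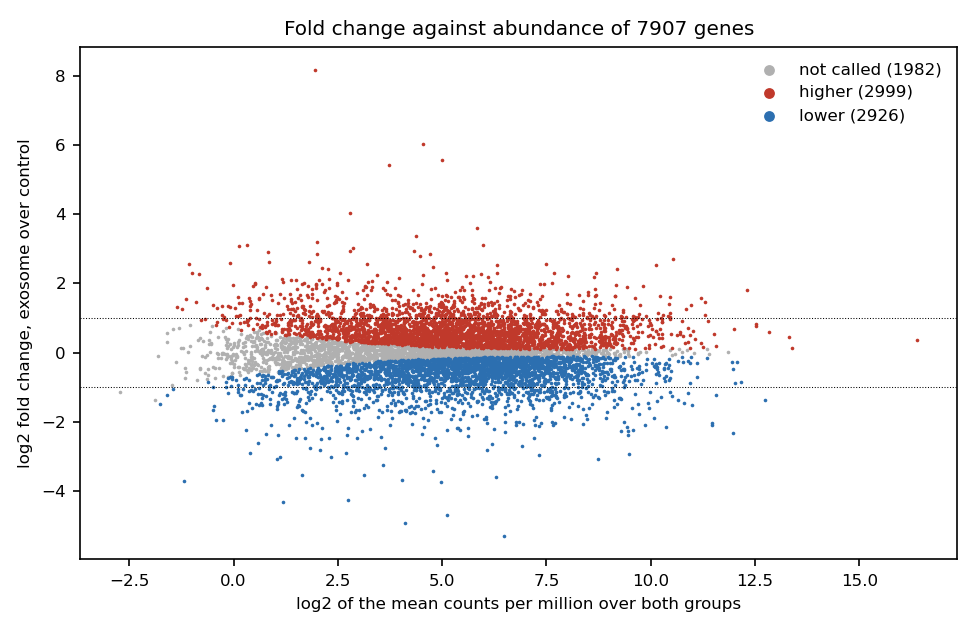
Each point is 1 of the 7907 tested genes, with the log2 of its mean CPM over both groups on the horizontal axis and its log2 fold change, exosome over control, on the vertical axis. Red points are the 2999 genes called higher, blue points the 2926 called lower and grey points the 1982 not called, and dotted lines mark 2-fold.

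Of 28 functional lists fixed before the data were examined, 25 were large enough to test, and the cytosolic ribosomal protein and ribosome biogenesis lists had the smallest camera p among them. Besides L1, ribosomal protein L7 (GL_Gan1_GLEAN_10003942) rose from 1120.1 ± 23.6 to 2894 ± 81.5 CPM and L7A/L8 (GL_Gan1_GLEAN_10009257) from 478 ± 22.3 to 1242 ± 20.2. The median log2 fold change of the 79 cytosolic ribosomal protein genes was 0.79, and 19 of them rose at least 2-fold. Adjusted over the list alone, 69 were higher and 3 lower. Ribosome biogenesis factors, which process and assemble ribosomal RNA, also rose as a list: 34 of 43 were higher, 4 lower and 5 not called, with 34 and 5 adjusted over the list alone. The list had a median of 0.69 and a camera adjusted p of 3.91e-07, but adjusted p = 0.0684 with an estimated correlation. Among its genes the pre-ribosomal RNA processing protein Urb2 (GL_Gan1_GLEAN_10005921) rose by a log2 fold change of 1.44 (SE 0.055) and the 20S pre-rRNA nuclease (GL_Gan1_GLEAN_10008120) by 1.53 (SE 0.068). Of 19 mitochondrial ribosomal proteins, 15 were higher and 1 lower, both over all genes and adjusted over the list alone, but the list was not called (camera adjusted p = 0.107). Its lower member was a gene described as protein S36 (GL_Gan1_GLEAN_10004221), which went from 1029 ± 25.2 to 216 ± 3.3 CPM, while MRP51 (GL_Gan1_GLEAN_10005654) rose from 17.1 ± 2.25 to 46.4 ± 2.31. The place of the S36 gene in the list rests on its description alone.

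Genes of the respiratory chain and ATP synthase rose as a list, with 37 of 52 higher, 12 lower and 3 not called, and 37 and 12 adjusted over the list alone. The median log2 fold change of the list was 0.51 and its camera adjusted p was 0.00795, but adjusted p = 0.458 with an estimated correlation. The F1 gamma subunit of ATP synthase (GL_Gan1_GLEAN_10005338) went from 304 ± 5.35 to 641 ± 6.27 CPM and the F1 alpha subunit (GL_Gan1_GLEAN_10004152) from 803 ± 4.31 to 1719.8 ± 95.9. Alternative oxidase (GL_Gan1_GLEAN_10000408), which passes electrons from ubiquinol to oxygen without pumping protons, went the other way, from 3005 ± 58 to 1058 ± 20.5 CPM.

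In central carbon metabolism the direction differed from gene to gene. Of 19 genes of the TCA and glyoxylate cycles, 6 were higher, 7 lower and 6 not called, the first 2 counts being equal when adjusted over the list alone, and the list was not called (camera adjusted p = 0.885). NAD-dependent isocitrate dehydrogenase (GL_Gan1_GLEAN_10001437) rose from 65.2 ± 4.51 to 258 ± 23.1 CPM and an aconitase-family protein (GL_Gan1_GLEAN_10005971) from 54.7 ± 1.96 to 174 ± 9.53. Malate synthase A fell by 2.09 on the log2 scale (SE 0.047), and a citrate synthase-like gene that the file annotates as 2-methylcitrate synthase (GL_Gan1_GLEAN_10003330) fell by 2.64 (SE 0.065). The glycolysis list held 42 tested genes, 14 higher, 18 lower and 10 not called, with 14 and 18 adjusted over the list alone, and was not called (camera adjusted p = 0.885). Its pattern also took in alcohol dehydrogenases, some described only by a zinc-type superfamily, so its counts do not describe glycolytic enzymes alone. The list member of smallest p, GL_Gan1_GLEAN_10009386, is described by a pyruvate kinase-type domain but carries the annotation of isocitrate lyase, the other enzyme of the glyoxylate bypass. It went from 4564 ± 114 to 1119 ± 17.8 CPM. An alcohol dehydrogenase (GL_Gan1_GLEAN_10008374) rose from 1343 ± 43.3 to 3739 ± 50.7.

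**Figure D2:**
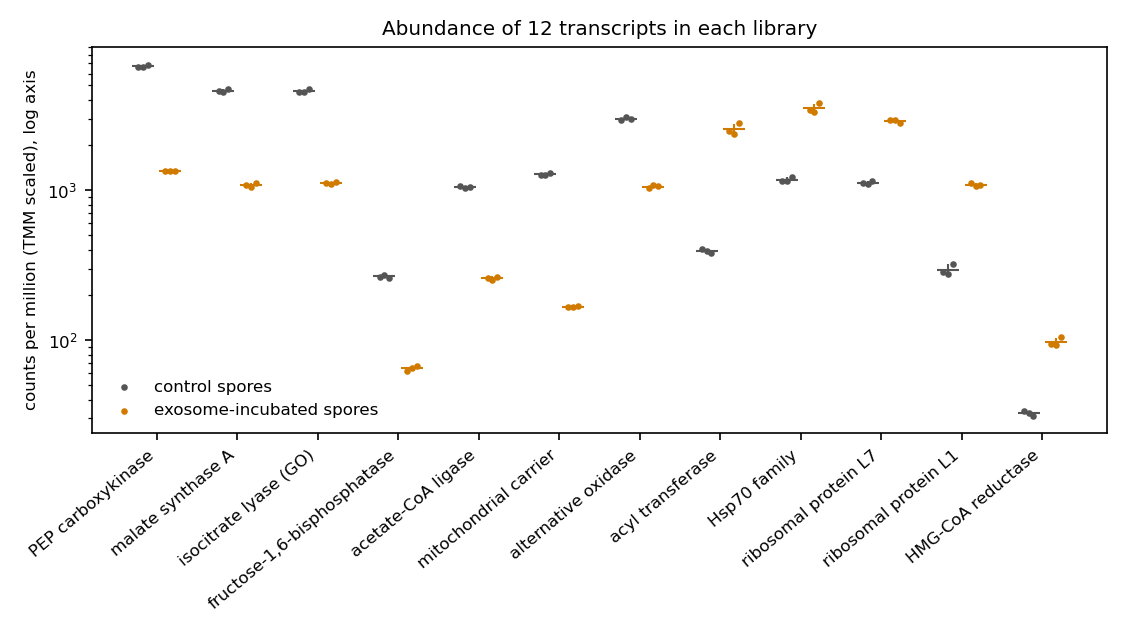
Points are CPM (log axis) of 12 transcripts in each of the 3 control (grey) and 3 exosome (orange) libraries, with the group mean as a horizontal bar and its SD as a vertical bar. Malate synthase A lies near 4603 in control and 1084 in exosome libraries, and ribosomal protein L7 near 1120.1 and 2894; the phosphoenolpyruvate carboxykinase, fructose-bisphosphatase, acetate-CoA ligase and mitochondrial carrier genes were chosen after their values were seen.

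The largest changes among genes with a named function included members of 1 efflux pump family that moved both ways. A CDR-type ABC transporter (GL_Gan1_GLEAN_10006833; scaffold 297, 61676 to 66231), of a family that exports drugs, rose from 1.32 ± 0.418 to 62.8 ± 1.12 CPM, a log2 fold change of 5.57 (SE 0.12; edgeR adjusted p = 2.36e-22). A different CDR-type transporter (GL_Gan1_GLEAN_10005046; scaffold 33, 278843 to 283803) fell from 66.5 ± 3.51 to 2.59 ± 0.508 CPM, a log2 fold change of -4.68 (SE 0.10; edgeR adjusted p = 2.21e-22). A C4-dicarboxylate transporter (GL_Gan1_GLEAN_10003243) rose from 3.64 ± 0.108 to 37.8 ± 0.803, an amino acid transporter (GL_Gan1_GLEAN_10003343) from 4.64 ± 0.532 to 35.4 ± 2.82 and an RTA-like membrane protein (GL_Gan1_GLEAN_10006126) from 6.38 ± 0.405 to 46.1 ± 1.01. A pair of adjacent acyl transferase genes annotated as fatty acid synthase (GL_Gan1_GLEAN_10004295 and GL_Gan1_GLEAN_10004294; scaffold 150) rose from 395 ± 11.5 to 2553 ± 229.7 and from 326 ± 19.8 to 1894 ± 154 CPM. The largest fall among described genes was that of a cytochrome P450 (GL_Gan1_GLEAN_10002373; scaffold 20, 62710 to 64801), from 176 ± 4.96 to 4.46 ± 0.207 CPM, a log2 fold change of -5.30 (SE 0.069; edgeR adjusted p = 7.35e-27). The next gene on the same scaffold, a fungal transcription factor (GL_Gan1_GLEAN_10002374), fell from 30.3 ± 2.84 to 2.36 ± 0.547, and another such factor (GL_Gan1_GLEAN_10002207) from 50.5 ± 2.27 to 4.71 ± 1.05. A GPR1/FUN34/yaaH family membrane protein (GL_Gan1_GLEAN_10004341) fell from 33.5 ± 2.74 to 1.1 ± 0.419 CPM, a hydrophobin (GL_Gan1_GLEAN_10007961) from 12.8 ± 0.731 to 0.657 ± 0.188 and a CFEM-domain extracellular protein (GL_Gan1_GLEAN_10004909) from 145 ± 13.4 to 11.9 ± 1.86. Of the genes described as glutathione-dependent formaldehyde-activating enzymes, which the antioxidant list also holds through their name, GL_Gan1_GLEAN_10000111 rose from 52.1 ± 3.04 to 306 ± 12.7 and GL_Gan1_GLEAN_10005809 fell from 58.7 ± 4.45 to 4.42 ± 0.317. An enoylreductase-domain gene (GL_Gan1_GLEAN_10004960) rose from 2.64 ± 0.53 to 15.8 ± 3.58. The hypothetical protein PITC_090990 (GL_Gan1_GLEAN_10002833) rose from 0.7 ± 0.119 to 45.8 ± 1.24 CPM, the largest rise among genes with a mean FPKM of at least 10 in the higher group.

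Calcium and MAP kinase signalling was the 1 list called lower, with 11 of 21 genes lower, 4 higher and 6 not called, with 11 and 4 adjusted over the list alone. Its median log2 fold change was -0.27 and its camera adjusted p 0.0469, but adjusted p = 0.366 with an estimated correlation. A calcium/calmodulin-dependent kinase-like gene (GL_Gan1_GLEAN_10007644) went from 1436 ± 12 to 525 ± 24.6 CPM, a sodium/calcium exchanger (GL_Gan1_GLEAN_10008584) from 137 ± 2.7 to 55.3 ± 3.97 and a histidine kinase (GL_Gan1_GLEAN_10005476) from 434 ± 21.2 to 196 ± 2.8. A voltage-dependent calcium channel (GL_Gan1_GLEAN_10005104) rose from 65.6 ± 1.93 to 160.3 ± 2.52. The list call was lost without control replicate 2 (camera adjusted p = 0.0539), exosome replicate 1 (0.0675) or exosome replicate 2 (0.0580), and under quantile normalization, median-of-ratios scaling and all limma settings, where camera adjusted p ranged from 0.0509 to 0.168.

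Proteasome and autophagy genes were lower more often than higher without a list call, and protease genes were split. Of 21 proteasome genes, 15 fell, 2 rose and 4 were not called, with 15 and 2 adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.0585). The 26S proteasome ubiquitin receptor (GL_Gan1_GLEAN_10005103) went from 312 ± 6.41 to 181 ± 8.8 CPM and the proteasome beta-subunit gene (GL_Gan1_GLEAN_10004268) from 201 ± 4.84 to 121 ± 2.1. The list was called lower without control replicate 3 (camera adjusted p = 0.0431) and under 8 other settings, with adjusted p between 0.00530 and 0.0430. Of 14 autophagy genes, 9 fell, 4 rose and 1 was not called, and adjusted over the list alone 10 fell and 4 rose (camera adjusted p = 0.539). Atg3 (GL_Gan1_GLEAN_10007820) fell by 0.76 on the log2 scale and Atg13 (GL_Gan1_GLEAN_10002089) by 0.69, while the lipid transfer protein Atg2 (GL_Gan1_GLEAN_10009277) rose from 189 ± 5.09 to 361 ± 23.5 CPM. Of 116 protease genes, 42 were higher, 46 lower and 28 not called, with 42 and 46 adjusted over the list alone (camera adjusted p = 0.885). The protease pattern also took in, by its description as an endopeptidase, the proteasome beta-subunit gene GL_Gan1_GLEAN_10004268, so the protease and proteasome lists overlap. A subtilisin-family peptidase (GL_Gan1_GLEAN_10005569) rose from 18.8 ± 0.773 to 87.9 ± 8.56 CPM and a peptidase of family S24/S26 (GL_Gan1_GLEAN_10005818) fell from 49 ± 1.59 to 17.8 ± 0.447.

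Conidium and dormancy genes held 10 lower, 4 higher and 4 not called of 18, with 10 and 4 adjusted over the list alone, and 5 fell at least 2-fold (median log2 fold change -0.38, camera adjusted p = 0.268). Hydrophobins coat the surface of dry spores, and all 3 named here fell: GL_Gan1_GLEAN_10007961 above, GL_Gan1_GLEAN_10008855 from 8.19 ± 0.93 to 2.79 ± 0.81 CPM and GL_Gan1_GLEAN_10008092 from 72.3 ± 2.05 to 49.1 ± 2.33. The Velvet factor gene (GL_Gan1_GLEAN_10002745), of a family of fungal developmental regulators, fell from 469 ± 10.5 to 264 ± 4.88. Polarised growth and cytokinesis genes were split, with 20 of 56 higher, 18 lower and 18 not called, and DNA replication and cell cycle genes likewise, with 18 of 44 higher, 18 lower and 8 not called; the higher and lower counts were equal to these when adjusted over the list alone. The pattern for polarised growth also took in, by its name, a Prp18-interacting splicing factor (GL_Gan1_GLEAN_10008890), which fell from 147 ± 3.96 to 77.8 ± 5.07 CPM. Its median of 0.025 and mean of 0.021 were positive while camera gave the direction as lower. Neither list was called (camera adjusted p = 0.963 and 0.973). Dynein heavy chain (GL_Gan1_GLEAN_10003047) rose from 87.8 ± 1.96 to 171 ± 12.8 and tubulin binding cofactor C (GL_Gan1_GLEAN_10008975) fell from 542 ± 12.6 to 154 ± 7.45 CPM. Anaphase-promoting complex subunit 1 (GL_Gan1_GLEAN_10006368) rose from 46.6 ± 1.66 to 146 ± 9.48 and the ribonucleotide reductase small subunit (GL_Gan1_GLEAN_10005744) fell from 117 ± 9.72 to 56.8 ± 0.912.

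Of 63 heat shock and chaperone genes, 30 rose, 20 fell and 13 were not called, with 31 and 21 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.107). An Hsp70 family gene (GL_Gan1_GLEAN_10006635) went from 1177 ± 49.2 to 3524 ± 256 CPM and a subunit of the TCP chaperonin (GL_Gan1_GLEAN_10003002) from 138 ± 2.99 to 262 ± 3.69. Antioxidant enzymes had 19 of 64 higher, 26 lower and 19 not called, with 19 and 26 adjusted over the list alone (camera adjusted p = 0.885). Catalase-peroxidase (GL_Gan1_GLEAN_10007760), which breaks down hydrogen peroxide, fell from 329 ± 11.2 to 76.5 ± 1.53 CPM, and a glutathione S-transferase (GL_Gan1_GLEAN_10007437) rose from 35.8 ± 2.65 to 132 ± 2.85. Of 15 sterol synthesis genes, 11 rose, 3 fell and 1 was not called, with 11 and 3 adjusted over the list alone, and the list was not called (median log2 fold change 0.47, camera adjusted p = 0.319). Hydroxymethylglutaryl-CoA reductase (GL_Gan1_GLEAN_10006786), the rate-limiting enzyme of the sterol pathway, rose from 32.7 ± 1.18 to 97 ± 6.87 CPM. Both squalene epoxidase genes, the enzyme blocked by allylamine antifungals, fell, GL_Gan1_GLEAN_10000391 by 0.97 and GL_Gan1_GLEAN_10000927 by 0.80 on the log2 scale. These 2 models span the same positions, 31857 to 33338, on scaffolds 74 and 43, so reads shared between copies leave their separate values uncertain.

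Cell wall glucan and chitin synthesis had 4 of 14 genes higher, 5 lower and 5 not called, with 4 and 5 adjusted over the list alone. Its median of 0.094 and mean of 0.0064 were positive while camera gave the direction as lower (adjusted p = 0.973). One chitin synthase (GL_Gan1_GLEAN_10006175) rose from 67.8 ± 6.41 to 98 ± 8.89 CPM and another (GL_Gan1_GLEAN_10000337) fell from 24.5 ± 0.454 to 17.2 ± 0.598. All 3 genes of the cell wall remodelling list, too few to test, were higher, also adjusted over the list alone. They were a CRH1-type family 16 glycoside hydrolase (GL_Gan1_GLEAN_10006713; log2 fold change 0.30), a family 81 glycoside hydrolase (GL_Gan1_GLEAN_10008591; 0.50) and GL_Gan1_GLEAN_10004258 (0.23), which by its description is a proteasome stabiliser and lost its call under all limma settings (adjusted p between 0.0950 and 0.118) and without replicate 3 of both groups (0.0894). Of 28 genes for plant cell wall degradation, 12 rose, 6 fell and 10 were not called, with 12 and 6 adjusted over the list alone (camera adjusted p = 0.539). A barwin-related endoglucanase (GL_Gan1_GLEAN_10006844) rose from 275 ± 9.37 to 851 ± 52.9 CPM, and the family 28 glycoside hydrolases GL_Gan1_GLEAN_10004813 and GL_Gan1_GLEAN_10005669, a family of pectin-cleaving enzymes, rose from 11.1 ± 0.876 to 22.2 ± 0.794 and from 14.2 ± 0.812 to 25.6 ± 1.35. The cellobiose dehydrogenase gene (GL_Gan1_GLEAN_10005545) fell from 48.2 ± 0.621 to 27.2 ± 0.573.

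Transporter lists moved both ways. Of 195 major facilitator genes, 62 rose, 80 fell and 53 were not called; of 33 ABC transporters, 16 rose, 11 fell and 6 were not called; of 53 amino acid transporters, 16 rose, 21 fell and 16 were not called. Adjusted over the list alone, the higher and lower counts of these 3 lists were equal to those over all genes, and none of the 3 was called (camera adjusted p = 0.885, 0.742 and 0.885). For the major facilitators the median log2 fold change was -0.13, the mean 0.010 and the camera direction lower. Of those named, GL_Gan1_GLEAN_10006839 fell from 1257 ± 13.3 to 265 ± 13.2 CPM and GL_Gan1_GLEAN_10002837 rose from 728 ± 20.4 to 1599 ± 42.4. An oligopeptide transporter (GL_Gan1_GLEAN_10003530) rose from 24.7 ± 3.05 to 113 ± 2.43 and the amino acid transporter GL_Gan1_GLEAN_10004472 fell from 118 ± 11 to 16.8 ± 2.39. The sugar transporter list matched only 2 tested genes by description, a nucleotide-sugar transporter (GL_Gan1_GLEAN_10007086) that fell from 53.5 ± 5.1 to 30.9 ± 1.88 and a maltose permease (GL_Gan1_GLEAN_10001205) that was not called, at 0.268 to 0.396 CPM. Adjusted over the list alone, 1 of the 2 was again lower. Of 10 iron and siderophore genes, 3 rose, 4 fell and 3 were not called, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.441). A zinc/iron permease (GL_Gan1_GLEAN_10006772) fell from 244 ± 11.4 to 57.2 ± 3.07 and another (GL_Gan1_GLEAN_10004189) rose from 211 ± 4.84 to 376 ± 3.77.

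Cytochrome P450 genes were split, with 21 of 52 higher, 20 lower and 11 not called, and 21 and 20 adjusted over the list alone (camera adjusted p = 0.268). After GL_Gan1_GLEAN_10002373, the largest fall among the named members was that of GL_Gan1_GLEAN_10006547, from 283 ± 13.3 to 36.1 ± 2.98 CPM. The NADPH-cytochrome P450 reductase gene (GL_Gan1_GLEAN_10003449) fell from 556 ± 3.26 to 185 ± 15.8. The list of secondary metabolite backbone enzymes had 13 of 32 genes higher, 11 lower and 8 not called, with 13 and 11 adjusted over the list alone; its median was 0.13, its mean -0.017 and its camera direction lower (adjusted p = 0.973). Of the 32, 26 matched by an enoylreductase domain name, and all 26 were annotated with dehydrogenase, oxidoreductase or zinc binding terms and 0 with a polyketide or phosphopantetheine term. The split of this list therefore says little about backbone enzymes. A terpenoid synthase (GL_Gan1_GLEAN_10005916) fell from 100.2 ± 3.61 to 39.3 ± 2.01. Endocytosis and vesicle traffic genes had 30 of 76 higher, 28 lower and 18 not called, with 30 and 29 adjusted over the list alone (camera adjusted p = 0.923). A vacuolar protein sorting gene (GL_Gan1_GLEAN_10006500) rose from 198 ± 8.98 to 619 ± 13.1 and eisosome protein 1 (GL_Gan1_GLEAN_10004241), of the plasma membrane furrows, fell from 903 ± 96.1 to 356 ± 13.7. RNA silencing genes were too few to test as a list: RNA-dependent RNA polymerase (GL_Gan1_GLEAN_10007955) rose from 13.7 ± 0.424 to 32.6 ± 1.46 CPM and ribonuclease III (GL_Gan1_GLEAN_10000058) fell from 51.3 ± 2.24 to 41.8 ± 1.4, and both calls held adjusted over the list alone. The ribonuclease III gene is not described as Dicer, so a part in RNA silencing is not shown. Median log2 fold changes of the TCA, P450, polarised growth, DNA replication and endocytosis lists lay near 0 and changed sign under at least 1 alternative setting.

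**Figure D3:**
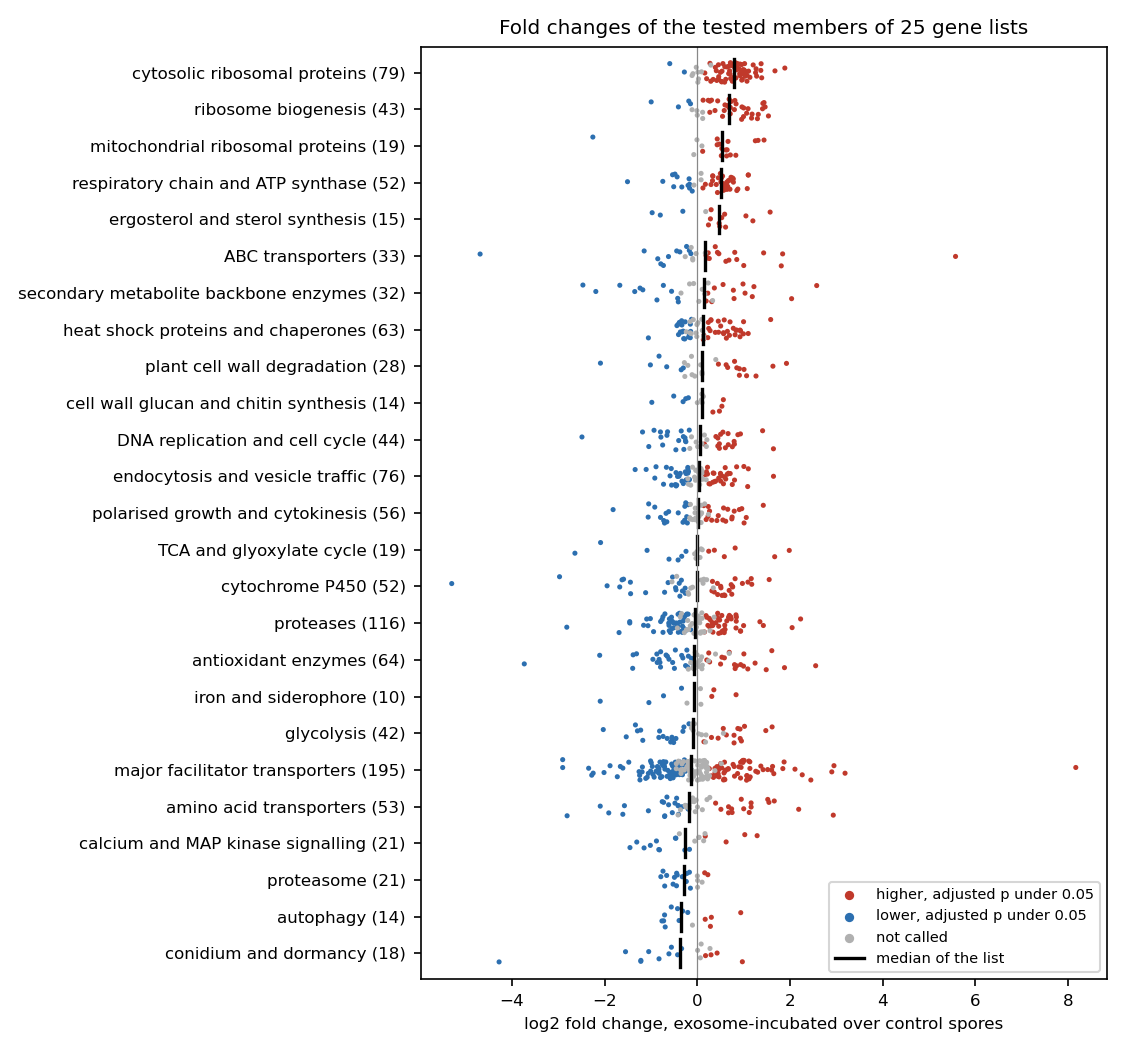
Each point is the log2 fold change, exosome over control, of 1 tested gene of 25 lists, with the number of tested genes in parentheses, red for genes called higher, blue for lower and grey for not called, and a black bar at the list median. The cytosolic ribosomal proteins have the highest median (0.79) and the conidium and dormancy genes the lowest (-0.38).

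Enrichment of annotation terms among the called genes, tested with Fisher's exact test, gave 50 terms for the higher genes and 21 for the lower genes out of 1111 GO and 108 KEGG terms. The test takes genes as independent, so genes that move together can make its p too small. The shares below stand against 42.0% of tested genes with a GO term and 43.5% of those with a KEGG pathway called higher. For lower calls these backgrounds were 34.9% and 34.0%. With Benjamini-Hochberg adjusted p in parentheses, the higher genes included 108 of 117 (8.21e-28) genes for structural constituents of the ribosome, 127 of 167 (6.38e-17) of the nucleolus and 55 of 85 (0.00411) of oxidative phosphorylation. They also included 15 of 18 (0.019) genes of tRNA aminoacylation, 9 of 9 (0.019) of arginine biosynthesis, 16 of 20 (0.0349) of lysine biosynthesis and 8 of 8 (0.0353) of purine (IMP) synthesis. Secondary metabolic process, with 23 of 32 (0.0244) genes, and phosphopantetheine binding, with 16 of 20 (0.0244), were among the higher terms as well. Ergosterol biosynthesis, with 19 of 25 (0.0244) genes higher, passed as a term although the shorter sterol list did not. The lower genes included 16 of 20 (0.00411) genes of carbon utilization, 13 of 14 (0.00113) of the phagophore assembly site, where autophagosomes form, 46 of 84 (0.00473) of yeast autophagy, 36 of 62 (0.00562) of ubiquitin-mediated proteolysis and 25 of 42 (0.0244) of the proteasome. Also among the lower terms were endocytosis, with 44 of 87 (0.0345) genes, and SNARE interactions in vesicular transport, with 13 of 17 (0.0190). Protein transport had 19 of 26 (0.00578) genes lower. The endocytosis and vesicle traffic list, matched by description and tested with camera, was split.

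In an enrichment test added after the data were seen, again Fisher's exact test but restricted to changes of at least 2-fold, oxidation-reduction process had the smallest adjusted p among the lower terms (55 of 442 genes, adjusted p = 1.80e-04). Acetate catabolism led by share (6 of 8 genes, adjusted p = 7.64e-04), and spore wall (4 of 6, adjusted p = 0.0349) was also among them. Further lower terms included transmembrane transport (33 of 272, adjusted p = 0.0228), threonine catabolism (5 of 9, adjusted p = 0.0228), and tyrosine and pyruvate metabolism. The KEGG ribosome pathway had the smallest adjusted p among the higher terms (29 of 111 genes, adjusted p = 9.17e-05).

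One transcript dominated all libraries. It encodes the hypothetical protein PITC_005760 (GL_Gan1_GLEAN_10000206; scaffold 263, 22177 to 22707), annotated to spore germination and the fungal cell wall, and took 7.63 ± 0.144% of counts in control and 9.49 ± 0.416% in exosome libraries. The 10 most abundant genes of each library together took 13.9 ± 0.210% and 16.1 ± 0.207%. Among the 5 genes of highest mean FPKM, the hypothetical protein PITC_014190 (GL_Gan1_GLEAN_10007698) fell from 9955 ± 452 to 3838 ± 94 CPM and a mitochondrial carrier annotated as an ATP:ADP antiporter (GL_Gan1_GLEAN_10007251) rose from 4346 ± 21.8 to 7369 ± 130.1. The glucose-repressible protein Grg1 (GL_Gan1_GLEAN_10005111) had a log2 fold change of -0.29 and an HSP20-like chaperone (GL_Gan1_GLEAN_10004266) of -0.27, both called lower, but quantile normalization turned these to 0.084 and 0.13.

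Calls rest on edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05, 2-sided. In 6049 of the 7907 genes (76.5%), all 3 libraries of 1 group lay above all 3 of the other, against 10% by chance, and the biological coefficient of variation was 0.0686. Counts and fold changes are relative to the rest of each library, so a change in total RNA per spore would not be seen. What the control spores received in place of the nanoparticle preparation is not given in the sources used here.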

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

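DESeq2, robust edgeR, scaling by library totals, removal of the most abundant gene and leaving out replicate 3 of both groups were chosen after the data were seen. Limma-trend on log2(FPKM + 1) was the test foreseen for a table without counts and became an alternative once counts were found. The other settings were planned. Over all settings the genes called higher numbered between 2254 and 3124 and those lower between 2310 and 3090. The lowest counts came from the FPKM filter of 10, which tested 5594 genes, and DESeq2 gave 2983 and 2943. Of the 5925 calls, 5555 to 5923 kept direction and call under the settings that used all libraries and tested at least 7906 genes, and 1 turned, under quantile normalization (the HSP20-like chaperone). No setting moved the median of all genes by over 0.1. Changes of at least 2-fold depended more on the scale: 200 higher and 331 lower with a pseudocount of 5, which shrinks folds of low genes by construction, 397 higher under limma with a pseudocount of 1 (with trend, robust or without trend), and 388 higher with the FPKM filter of 10. Leaving out each library in turn gave 2859 to 2919 higher, 2767 to 2893 lower, 609 to 628 higher and 562 to 602 lower at least 2-fold, and 3 to 5 lists. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05) and fry 17. The replicate number as a block gave 3015 higher and 2934 lower and kept 5894 of the calls. Same-numbered control and exosome libraries correlated in their deviations at 0.0027, 0.044 and 0.041, so the numbers were not taken as pairs, although each library correlated best with its own number except control replicate 1 and exosome replicate 1. Replicate 3 of both groups stood apart: on the second principal component (3.27% of variance) these 2 libraries lay at -9.36 and -8.52 and the others between 1.86 and 6.77, and within groups the chi-square per gene was 6.88 and 7.30 for replicates 1 and 2 and 17.7 to 22.2 for pairs with replicate 3. A batch shared by same-numbered libraries is therefore not excluded. Without replicate 3 of both groups, 2957 genes were higher and 2921 lower, 5636 of the calls were kept and 7 lists were called, the 4 of the main test and the heat shock (camera adjusted p = 0.0443), mitochondrial ribosomal (0.0339) and proteasome (0.0167) lists.

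Among named genes, 2667 values under alternatives kept direction and call, 8 lost the call and 2 turned: Grg1 (0.084) and the HSP20-like chaperone (0.13) under quantile normalization, which also sets the most abundant gene to 0 by construction. Among lists, 472 values kept direction and call, 10 lost it, 17 gained it and 26 turned, all of them medians of lists that were not called; the cause was not tested. Polarised growth turned to -0.022 and -0.014 (pseudocounts 0.1 and 5), -0.031 (FPKM filter of 10), -0.019 (limma, all 3 settings with pseudocount 1), -0.012 (library totals), and ran from -0.0087 to 0.018 with each library left out. Endocytosis turned to -0.00060 (pseudocount 0.1), -0.021 (FPKM filter of 10) and -0.00045 (limma, the same 3 settings). DNA replication turned to -0.24 with the FPKM filter of 10. The P450 list turned to 0.096 without a filter, 0.020 with upper quartile scaling, 0.015 without replicate 3 of both groups, and ran from -0.076 to 0.047 with each library left out. The TCA list turned to 0.017 without a filter, 0.023 with the FPKM filter of 10, 0.022 with upper quartile scaling, 0.018 with quantile normalization, and ran from -0.058 to 0.052 with each library left out. The mitochondrial ribosomal list also gained its call under 6 settings on log2 FPKM (camera adjusted p between 0.00132 and 0.00827). At 10 CPM, counting alone limits a library's precision to a coefficient of variation of 4.14 to 4.39%.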

Other observations

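The tests in this part, apart from the splits of the libraries, were chosen after the gene-wise results had been seen, as were all genes named here that the rule does not take. Acetyl-CoA carboxylase (GL_Gan1_GLEAN_10005381; scaffold 71, 183382 to 190359), which makes malonyl-CoA for fatty acid synthesis, went from 185 ± 6.05 to 993 ± 102 CPM, a log2 fold change of 2.42 (SE 0.06), beside 2.69 and 2.54 for the adjacent pair annotated as fatty acid synthase (GL_Gan1_GLEAN_10004295 and GL_Gan1_GLEAN_10004294). The KEGG fatty acid biosynthesis pathway as a whole went both ways: of its 23 tested genes 10 were higher, 9 lower and 4 not called, 3 were at least 2-fold higher, namely these 3, 4 were at least 2-fold lower, and the median was 0.075. Those 4 were a cytochrome P450 (GL_Gan1_GLEAN_10002328; 58.7 to 19.0 CPM) and dehydrogenases of low abundance. The latter, GL_Gan1_GLEAN_10006990, GL_Gan1_GLEAN_10006050 and GL_Gan1_GLEAN_10006923, had 4.77, 4.29 and 2.41 CPM in control libraries. A further gene annotated to fatty acid synthase (GL_Gan1_GLEAN_10008046) fell by 0.41 on the log2 scale.

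Single genes of gluconeogenesis and of acetate and ethanol use fell, while the alcohol dehydrogenases GL_Gan1_GLEAN_10008374 and GL_Gan1_GLEAN_10005842 rose, the latter from 53.3 ± 5.08 to 163 ± 8.87 CPM, and another alcohol dehydrogenase (GL_Gan1_GLEAN_10008123) fell from 142 ± 8.3 to 63 ± 0.74. ATP-dependent phosphoenolpyruvate carboxykinase (GL_Gan1_GLEAN_10002979), the entry to gluconeogenesis, went from 6719 ± 147 to 1341 ± 6.31 CPM, fructose-1,6-bisphosphatase (GL_Gan1_GLEAN_10002610) from 266 ± 6.91 to 64.6 ± 2.46, acetate-CoA ligase (GL_Gan1_GLEAN_10002915) from 1051 ± 8.52 to 259 ± 6.68 and a mitochondrial carrier (GL_Gan1_GLEAN_10003386) from 1274 ± 21.3 to 167 ± 1.14. On scaffold 11, from 42556 to 53675, 5 adjacent genes all fell at least 2-fold: the aldehyde dehydrogenases GL_Gan1_GLEAN_10004337 and GL_Gan1_GLEAN_10004338, a gene annotated as alcohol dehydrogenase (GL_Gan1_GLEAN_10004339), the hypothetical protein PITC_032410 (GL_Gan1_GLEAN_10004340) and the GPR1/FUN34/yaaH gene GL_Gan1_GLEAN_10004341. Their log2 fold changes ran from -1.88 to -4.93. Of 22 tested genes with the KEGG orthology entry for a hexose symporter family, 13 were lower, 4 higher and 5 not called (median -0.48), with GL_Gan1_GLEAN_10007726 the highest at a log2 fold change of 2.48.

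The number of called genes was set against other groupings of the 6 libraries. With edgeR the real split called 5925 genes (6023 at an unadjusted p under 0.05) and the highest of the other splits 0 (38 at an unadjusted p under 0.05), so 1 of the 10 splits, the real one, called as many. With 10 splits the share cannot fall under 0.05. The other splits each put control and exosome libraries on both sides, so the difference between the groups counted as spread within a side. Their 0 calls therefore say little about how the calls of the real split arose.

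The first pattern weighed is the rise of ribosomal genes. The 121 ribosomal protein and biogenesis genes had a median log2 fold change of 0.73, with 103 higher and 6 lower. Short, abundant transcripts can shift together for technical reasons, but 10000 gene sets matched on transcript length and abundance gave medians between -0.19 and 0.093 (their middle 95%), which argues against length or abundance as the cause. A hypothesis left open is that the treated spores may have moved further towards germination or growth, which a nutrient in the preparation could also bring about. Other lists do not settle it, since 10 of 18 conidium and dormancy genes fell while DNA replication and cell cycle genes were split, 18 higher and 18 lower.

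The second pattern is the fall of acetate and carbon utilization genes, 17 lower and 4 higher of 21, with a median of -0.79, a set put together from terms whose genes fell, so its distance from other genes is no test. Sets of other genes matched for length and abundance had medians between -0.37 and 0.32 (middle 95%), centred at -0.025, so those features alone did not go with a fall. A candidate explanation is a readily used carbon source carried over with the juice vesicles, since sugars repress such genes in fungi. It was tested on the 58 genes of KEGG fatty acid degradation: 20 were higher, 20 lower and 18 not called, with a median of 0.061. Both bounds set beforehand against the explanation, a median of 0 or above or at least as many higher as lower calls, were met, so its prediction failed for this pathway. The bounds made no provision for members that go both ways. A thiolase-like gene (GL_Gan1_GLEAN_10006171) rose by 2.21 on the log2 scale and acyl-CoA oxidase (GL_Gan1_GLEAN_10002238) by 1.04, while an acyl-CoA dehydrogenase (GL_Gan1_GLEAN_10006376) fell by 1.78. Members that fell also included aldehyde and alcohol dehydrogenases, some of them from the scaffold 11 run. The failed prediction thus does not exclude a carbon source. Without a control preparation, a carbon source and an effect of the vesicles cannot be told apart here.

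The third pattern is that neighbouring genes changed together. Across 6885 adjacent pairs of tested genes, which are not independent replicates, log2 fold changes correlated at r = 0.141, against -0.025 to 0.024 in 1000 random orders. Reads running across neighbouring models may add to this, but 755 divergent pairs at least 1000 bases apart with different descriptions still gave r = 0.114 (random orders -0.073 to 0.067), which argues against it as the whole cause. Pairs within 5 genes of a secondary metabolite backbone gene gave r = 0.269 over 261 pairs (other pairs 0.0051 to 0.264), but 0.0858 without the scaffold 11 genes, below the 0.133 of all pairs without them, and 26 of the 32 list members are annotated as dehydrogenases or the like, so co-regulated metabolite clusters stay open. Runs of at least 4 neighbours changed at least 2-fold in 1 direction numbered 3, holding 13 genes, and 4 of 1000 random orders gave as many.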
